A study of Mus musculus with 2 samples.

How the data were processed

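MicroRNA sequencing was available for 2 libraries of 1 group, hippocampus of female B6CASTF1/J mice aged 2 months, and both libraries were assigned to the group and numbered as biological replicates 1 and 2 from the labels. The authors deposited 1 table of whole-number read counts per library, not normalized and not pooled, over miRNA genes of the mouse build mm10 and the GENCODE M21 annotation, per the deposited notes. The aligner, its version and the trimming of adapters are not given in the sources used here. Each deposited table has 3 columns of counts, without regard to strand, on the sense strand and on the antisense strand, and 4 leading lines with totals of reads given to no gene. The roles of the columns are not named in the tables and were read from the values. The sense column was taken as the strand column with the larger total, a rule set before the data were examined, and it is the column used unless another is named.

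The totals of reads given to no gene were left out of library sizes and tests. In the sense column, reads mapping to several places made up 45.9% of all reads in replicate 1 and 48.4% in replicate 2, unmapped reads 11.8% and 11.2%, and reads outside the annotated genes 3.60% and 3.69%. Reads on miRNA genes made up 38.7% and 36.7%. Because reads that map to several places carry no gene in these tables, miRNAs with several identical gene copies are undercounted, and the 1087 genes that share 20 or more identical bases with a miRNA gene elsewhere, which held 10.3% of the counts, are uncertain. Among the genes named in the text these include Mir26a-2, Mir128-1, Mir23a, Mir23b, Mir27b, Mir194-2, Mir487b, Mir92-1, Mir146, Mir302a, the Mir138, Mir219a, Mir29b and Mir9 genes, Mir29c and the Sfmbt2 families. The counts are per gene, so the 2 arms of a hairpin are not separated. The animals are hybrids with a castaneus-derived strain while mm10 is a C57BL/6J genome, and how reads with strain differences were mapped is not given in the sources used here. In the column without regard to strand, reads on the 64 genes that overlap a miRNA gene on the other strand are ambiguous, and 27 genes with 10 or more sense counts kept less than 10% of them there.

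Gene symbols, positions, hairpin sequences and host genes were taken from GENCODE M21, and all 2202 identifiers were found. Host gene and exon or intron status refer to a gene on the same strand that contains the hairpin. Levels are given as CPM, counts per 1000000 sense counts on miRNA genes, and as percent of those counts, with the mean and SD over both libraries and a 95% Wilson interval where 1 library is quoted. A count of 0 was read as allowing up to 3 counts. Ratios are replicate 2 over replicate 1 on the scale log2(CPM + 0.5), and their 95% intervals are exact binomial intervals of the 2 counts. Intervals cover counting error only.

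With 1 group of 2 libraries there is no condition to test, so edgeR's quasi-likelihood test does not apply. Genes with at least 10 counts in both libraries were compared by a two-sided Fisher's exact test of the gene against all other counts on miRNA genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where another scaling was tried, the exact binomial test at the ratio of the scaled totals took its place. The spread between the libraries was estimated as the common dispersion of edgeR with an intercept-only design and TMM factors. The median log2 ratio of a list was set against 10000 random lists of tested genes of the same size matched on mean expression in 10 bins, for lists with at least 3 tested genes. The random lists draw genes singly and ignore that genes of 1 cluster may vary together. Leaving out a replicate leaves 1 library, which gives shares but no ratios.

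The lists were written before the data were examined: neuron-enriched, miR-9 family, activity-regulated or dendritic, astrocyte-associated, oligodendrocyte, microglia and leukocyte, endothelial and mural, choroid plexus and ependyma, erythroid, regions outside hippocampus, other organs, let-7 family, Dlk1-Dio3 imprinted cluster, Sfmbt2 intron cluster families, miR-17~92 and paralogues, pluripotent cell clusters, and testis X-linked cluster, 17 in all. The genes named in the text are the 20 with the highest mean CPM, up to 4 members of each list with the highest mean CPM, and the 10 with the largest and the 10 with the smallest log2 ratio among the 162 genes past the threshold with a mean of 100 CPM or more. The miR-124 genes, Mir10a, Mir141, Mir200a, Mir200b, Mir496b, Mir296, Mir192 and Mir194-2 fall outside this rule and were named after their values were seen. So were the genes of the miRNA families in the closing section. The alternatives were the column without regard to strand, a minimum of 1, 5 or 100 counts, no filter, TMM and DESeq2 size factors, a deeper library thinned to 4517648 counts, pseudocounts of 1 and 5 CPM, a denominator without the most abundant gene, and leaving out each replicate.

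The Fisher test was checked on simulated data with counting error only, drawn for the real genes at the real depths with 200 changed genes. In a step on 417 genes it called 54.2% of the genes changed 1.2-fold, 70.0% of those changed 1.5-fold, 85.7% of those changed 2-fold, 100% of those changed 4-fold and 0.448% of the unchanged ones. Simulated coefficients of variation of 0.1 and 0.3 were estimated by edgeR as 0.0944 and 0.302. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.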

Results

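Small RNAs were sequenced from the hippocampus of female B6CASTF1/J mice aged 2 months, which are F1 hybrids between a common laboratory strain and a castaneus-derived strain, and the reads were counted over annotated microRNA (miRNA) genes. The labels call the tissue a layer of hippocampus without naming the layer. The series holds 1 group of 2 libraries, biological replicates 1 and 2, with separate tissue records and 1 shared donor record. The labels do not state that the tissue came from different animals, so the spread between the libraries may be partly technical. No treatment or other group is named, so the data describe the miRNA content of this tissue, and the comparison that the design allows is the one between the replicates. Replicate 1 held 11666435 reads, of which 4517648 fell on the sense strand of a miRNA gene. Replicate 2 held 16280072 reads, of which 5979247 did. A count of 0 allows a level of up to 0.664 counts per 1000000 counts on miRNA genes (CPM) in replicate 1 and 0.502 CPM in replicate 2. Intervals and these floors cover counting error only, since amplified reads are not independent molecules.

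Reads that map to several places, 45.9% of all reads in replicate 1 and 48.4% in replicate 2, carry no gene, so all shares and ranks hold among reads that map to 1 place. Among these, the counts were led by the let-7 family, which represses growth and developmental timing genes and is abundant in differentiated tissue. Its 12 genes held 37.6% ± 1.70 (SD, n = 2) of all counts on miRNA genes. At least 1 member of the family shares 22 bases with a copy, and such a stretch lies in both genes, so more than 1 gene is affected. The family share and the ranks within the family are therefore uncertain too. Mirlet7g (ENSMUSG00000065440.1), which lies at positions 106178840 to 106178927 of chromosome 9 in an intron of Wdr82, held 12.4% ± 0.764 and was the most abundant gene. Mirlet7b on chromosome 15 (85707319 to 85707403, in an exon of the non-coding gene Lncppara) followed with 10.2% ± 0.197. Mir139, which sits in an intron of the phosphodiesterase gene Pde2a on chromosome 7 (101475376 to 101475443), held 8.04% ± 1.04. Mirlet7i and Mirlet7d held 6.46% ± 0.688 and 4.40% ± 0.224, and Mir744, in an intron of Map2k4, held 3.40% ± 0.818. Mir127 of the imprinted Dlk1-Dio3 region, Mirlet7e, Mir99a and Mir23b completed the 10 most abundant genes, at 3.10%, 2.81%, 2.66% and 2.27%. These 10 genes took 55.8% ± 0.940 of the counts, with 56.4% in replicate 1 and 55.1% in replicate 2. The next 10 were Mir132, Mir125a, Mir29a, Mir191, Mir126a, Mir22, Mir128-1, Mir151, Mir330 and Mir221, from 2.04% ± 0.538 for Mir132 down to 1.04% ± 0.0175 for Mir221. Of 2202 annotated miRNA genes, 420 had at least 10 counts in both libraries and 1428 had none in either. A further 147 genes were seen in 1 library only, none with more than 13 counts. The 93 genes at 1000 CPM or more held 95.1% of the counts.

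Neuron-enriched miRNAs formed the largest of the cell type lists, at 5.25% ± 0.281 of counts over 15 genes. Mir132, which is induced by neuronal activity, reached 20435 ± 5384 CPM (SD, n = 2), Mir128-1 in an intron of R3hdm1 reached 12311 ± 1602 CPM, and Mir137 reached 8276 CPM. Mir138-1 followed at 4056 CPM. The genes of miR-124 and miR-9, known as abundant neural miRNAs, were counted at low levels. The miR-124 genes on chromosomes 14, 3 and 2 had 13 and 9, 4 and 0, and 2 and 3 counts in replicates 1 and 2. The miR-9 family held 0.0105% ± 0.00323, led by Mir9-3 with 343 and 650 counts, then Mir9-1 with 22 and 101 and Mir9-2 with 5 and 12. The miR-124 genes share an identical stretch of 32 bases and the miR-9 genes stretches of 26 to 33 bases with a copy elsewhere, and reads that map to several places were left out of the deposited counts. Their values, and those of the other genes with copies, are therefore uncertain. Among them, Mir128-1 and both Mir138 genes share 23 or 24 bases with a copy. The list of activity-regulated or dendritic miRNAs, which shares 4 genes with the neuron-enriched list and 4 with the Dlk1-Dio3 list, held 3.14% ± 0.429, with Mir132, both Mir138 genes and Mir485 at the top.

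The glial and vascular lists held smaller totals than the neuron-enriched list, although Mir29a and Mir126a had a higher mean CPM than every neuron-enriched gene but Mir132. The miR-29 family, listed as astrocyte-associated, held 1.70% ± 0.121, of which Mir29a on chromosome 6 (31062660 to 31062747) made up 1.51% ± 0.0503, while Mir29c reached 1711 CPM and the copies Mir29b-2 and Mir29b-1 76.2 and 63.3 CPM. The endothelial and mural list held 2.08% ± 0.219, led by Mir126a in the endothelial gene Egfl7 at 12438 ± 1630 CPM and by Mir143 at 8024 CPM, with Mir145a at 311.7 CPM and Mir145b at 1 count in replicate 2. The oligodendrocyte list held 0.676% ± 0.0319, nearly entirely from Mir338 in an intron of Aatk (4127 ± 201.4 CPM) and Mir219a-2 (2623 ± 518 CPM), both tied to myelinating cells. Mir219a-1 stood at 8.72 CPM, and Mir219b on the other strand of Mir219a-2 had 0 and 4 counts. Microglial and leukocyte miRNAs held 0.191% ± 0.0213, of which Mir150 at 1062 CPM and Mir146 at 740.8 CPM were the most abundant, followed by Mir142 at 66.1 CPM and Mir155 at 26.5 CPM. The choroid plexus and ependyma list held 0.176% ± 0.0370, with Mir204 in an intron of Trpm3 at 997.2 ± 218.7 CPM, Mir34c at 647.7 CPM, Mir449a at 92.6 CPM and Mir34b at 23.9 CPM. Red cell miRNAs held 0.0119% ± 0.00333, with Mir451a at 78.1 CPM, Mir486 at 21.6 CPM, Mir144 at 19.2 CPM and Mir451b at 0 counts in both libraries.

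Further lists, among them those of tissues other than forebrain, were set beside these levels. They do not mark a floor, since the erythroid list, at 0.0119%, lay below the list of other organs. The list of other organs held 0.0443% ± 0.00175 and 4 of its 16 genes had no count, with the islet miRNA Mir375 at 256.3 CPM, the skin miRNA Mir203 at 88.0 CPM, the muscle miRNA Mir206 at 54.2 CPM and the liver miRNA Mir122 at 38.7 CPM. The list of brain and cord regions outside hippocampus held 0.0448% ± 0.0312, with the libraries far apart. In the testis X-linked cluster 15 of 22 genes had no count, and the list held 0.00110% ± 0.0000803, with Mir547 at 7.64 CPM and Mir201, Mir741 and Mir471 below it. In the clusters of pluripotent cells 10 of 14 genes had no count, and the list came to 9 counts in replicate 1 and 7 in replicate 2, a share of 0.000199% (95% Wilson interval 0.000105 to 0.000379) and 0.000117% (0.0000567 to 0.000242). Its highest gene, Mir302a, had 6 and 0 counts, and Mir302d, Mir302b and Mir302c had at most 3 in a library. The miR-17~92 cluster and its paralogues, associated with proliferation, held 0.308% ± 0.00691, led by Mir93 in Mcm7 at 1295 CPM, Mir17 at 584.7 CPM, Mir106b at 476.3 CPM and Mir92-1 at 396.4 CPM. The miR-297, miR-466, miR-467 and miR-669 families, which include a cluster within an intron of the imprinted gene Sfmbt2, held 0.148% ± 0.0122 although 67 of the 81 genes had no count. Mir467d, Mir669c, Mir467e and Mir669o, the most abundant among them, share 36 to 60 bases with copies, so their counts are uncertain.

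**Figure D1:**
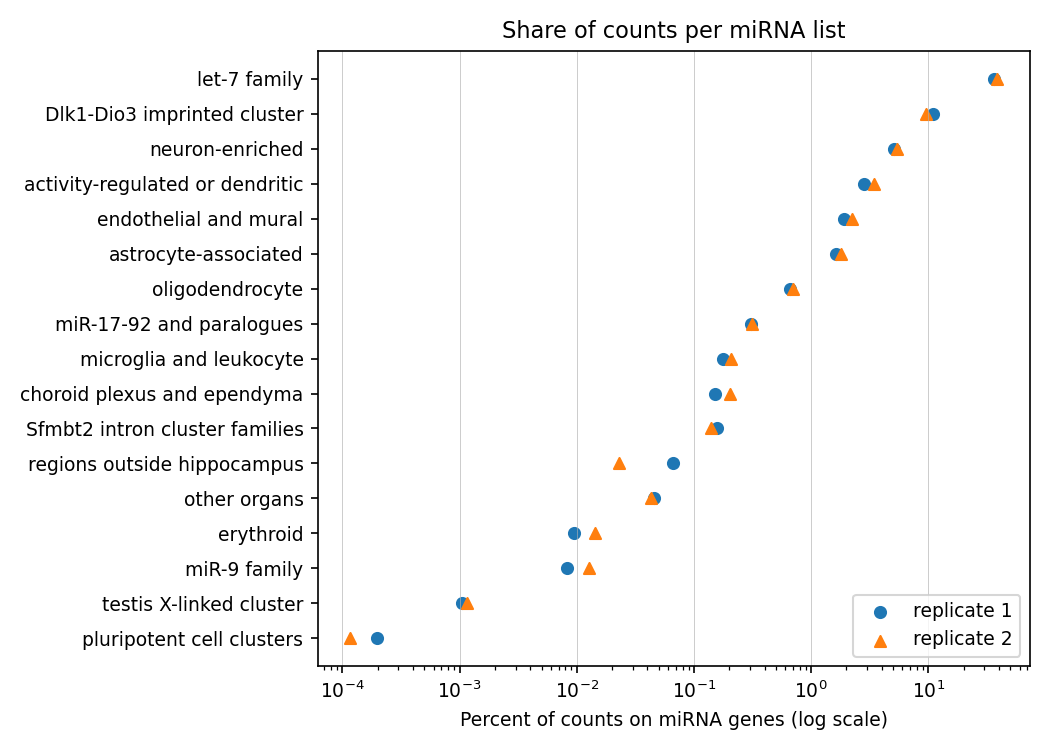
Share of the counts on miRNA genes held by each of the 17 miRNA lists, in percent on a log axis, with a circle for replicate 1 and a triangle for replicate 2. The let-7 family lies at 36.4% and 38.8%, the pluripotent cell clusters lie near the floor, and the list of regions outside hippocampus shows the widest gap, from 0.0668% in replicate 1 to 0.0227% in replicate 2.

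The imprinted Dlk1-Dio3 region, whose miRNAs are expressed from the maternal chromosome, held the second largest share among the lists, at 10.2% ± 1.05 (SD, n = 2). The list holds 54 genes between positions 109563692 and 109747960 of chromosome 12 and Mir496b on chromosome 19, which had no count. Mir127 reached 30961 ± 7937 CPM, Mir433 8083 ± 1022 CPM, Mir382 8073 ± 342 CPM and Mir487b 7791 ± 701 CPM, and 49 of the 55 genes had at least 10 counts in both libraries. The list held 10.9% of replicate 1 (95% Wilson interval 10.913 to 10.971) and 9.46% of replicate 2 (9.4394 to 9.4863). Of the 49 genes, 27 were lower and 13 higher in replicate 2 by Fisher's exact test of the reads of these libraries, 9 did not pass the threshold, and the counts adjusted over the list alone were 27 and 13 as well. They were 26 and 14 with TMM and 26 and 15 with DESeq2 size factors. Mir127 was 1.44-fold higher in replicate 1 and Mir370, in an intron of the non-coding gene Rian, 1.65-fold, whereas Mir380 was 2.49-fold higher in replicate 2. The list's median log2 ratio of -0.16 lay at percentile 2.80 of 10000 random lists of the same size matched on mean expression. Those lists draw genes singly, whereas the 49 genes lie in 1 region and may vary together, so the percentile can overstate how unusual the list is.

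**Figure D2:**
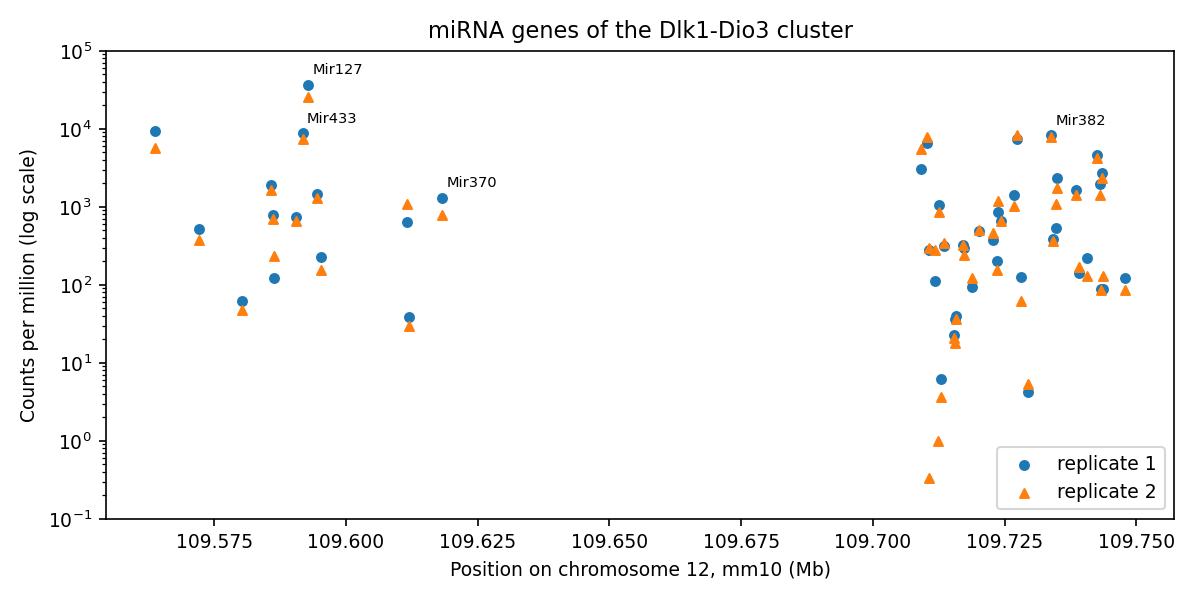
CPM on a log axis for the miRNA genes of the Dlk1-Dio3 cluster by position on chromosome 12 (mm10, in Mb), with a circle for replicate 1 and a triangle for replicate 2, and values of 0 not drawn. Mir127 is highest at 36573 CPM in replicate 1 and 25349 CPM in replicate 2, and the listed genes fall into a left and a right group with an empty stretch between them.

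The replicates were then set against each other to see which miRNAs differed by more than counting error. A two-sided Fisher's exact test of each gene against all other miRNA counts, adjusted by Benjamini and Hochberg at a threshold of 0.05, compares these 2 libraries and not any condition. Of the 420 genes tested, 239 differed, with 114 higher and 125 lower in replicate 2. The share higher was 47.7% and turned with the scaling, to 51.7% with TMM factors and 52.5% with DESeq2 size factors. The median fold of these 239 genes was 1.38, and 41 differed 2-fold or more. Over all 420 genes tested the median was 1.23-fold, and 315 lay within 1.5-fold. The 20 most abundant genes all passed the threshold, with ratios of replicate 2 to replicate 1 between 0.693 and 1.46. Mir221 was the 1 gene of the 20 that did not pass with the other scalings, where its log2 ratio of -0.03 became 0.003 with TMM (adjusted p = 0.821) and 0.0086 with DESeq2 size factors (adjusted p = 0.451). Mir137 did not pass, at a log2 ratio of -0.0008 (95% interval -0.02 to 0.02) that changed sign and passed the threshold with these scalings.

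Among the genes at 100 CPM or more that were higher in replicate 2, Mir26a-2, in an exon of Ctdsp2 on chromosome 10 (126995530 to 126995613), had the largest ratio. It had 65 counts in replicate 1 and 3497 in replicate 2, a log2 ratio of 5.30 (95% interval 4.99 to 5.72), and it shares 25 bases with another copy, so the value is uncertain. Mir674 was 3.87-fold higher, Mir21a, a miRNA of reactive and proliferating cells within Vmp1, 3.69-fold, Mir1839 3.42-fold, Mir140 within the ligase gene Wwp2 2.91-fold, and Mir340 in an intron of Rnf130 2.90-fold. Mir298, Mir31, Mir380 and Mir195a were 2.79-fold, 2.76-fold, 2.49-fold and 2.18-fold higher. In the other direction, Mir185 in an intron of Tango2 on chromosome 16 (18327401 to 18327465) was 7.69-fold higher in replicate 1, with 6831 against 1173 counts and a log2 ratio of -2.94 (95% interval -3.04 to -2.86). Mir153, in an intron of the neuroendocrine gene Ptprn2, was 3.80-fold higher in replicate 1 and Mir222 2.67-fold. Mir149 in an intron of Gpc1, Mir99b, Mir1224, Mir500, Mir377, Mir23a and Mir370 were 1.93-fold, 1.84-fold, 1.78-fold, 1.68-fold, 1.68-fold, 1.68-fold and 1.65-fold higher in replicate 1. The adjusted p from Fisher's exact test was 2.8e-75 for Mir340 and 1.4e-30 for Mir1224, and for most of the others it was below the smallest number that could be held.

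**Figure D3:**
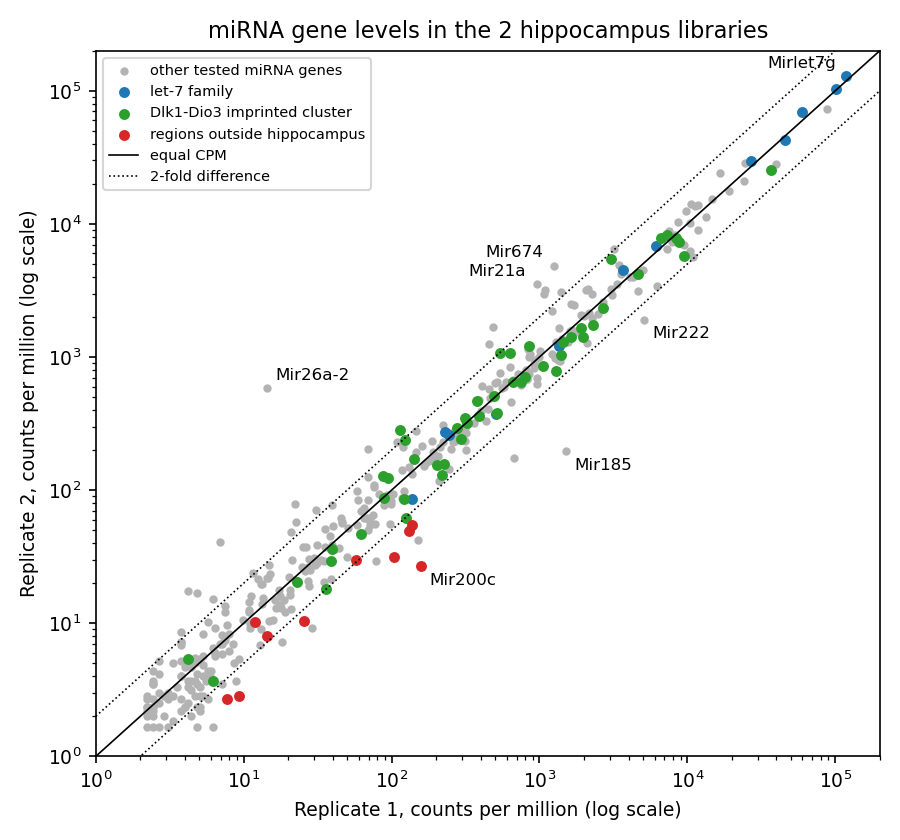
Each point is 1 of the 420 tested miRNA genes, with its CPM in replicate 1 on the horizontal and in replicate 2 on the vertical log axis; the solid line marks equal levels and the dotted lines a 2-fold difference. Most genes lie between the dotted lines, Mir26a-2 and Mir185 lie far outside them, and the 10 tested genes of the list of regions outside hippocampus lie below the solid line.

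Of the fixed lists, the one for brain and cord regions outside hippocampus differed most. It made up 0.0668% of replicate 1 (95% Wilson interval 0.0645 to 0.0693) and 0.0227% of replicate 2 (0.0216 to 0.0240), 2.94-fold more in replicate 1. Of its 10 tested genes, 9 were lower in replicate 2, none was higher and Mir10a did not pass (log2 ratio -0.22, adjusted p = 0.504 by Fisher's exact test). The counts adjusted over the list alone were 9 and 0. The median log2 ratio was -1.35, and none of 10000 matched random lists had a median as low. Those lists draw genes singly, whereas most of the tested list members are close neighbours. Mir141 and Mir200c lie 336 bases apart, Mir429 and Mir200a 908, Mir200a and Mir200b 695, and Mir182 and Mir183 3675. Neighbours may vary together, so the random lists can make the median look rarer than it is. Mir200c of the epithelial miR-200 family stood at 158.3 CPM in replicate 1 and 26.9 CPM in replicate 2, and Mir429 stood at 131.5 and 49.5 CPM. The sensory miRNAs Mir183 and Mir182 stood at 138.4 and 54.7 CPM and at 104.5 and 31.6 CPM.

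The let-7 family had 7 of 12 genes higher and 4 lower in replicate 2, with a median log2 ratio of 0.10 at percentile 79.4. The neuron-enriched list had 1 gene higher, 7 lower and 4 not past the threshold among 12 tested, and its median log2 ratio of -0.07 (percentile 36.4; -0.03 with either other scaling) had the opposite sign to the log2 ratio of its summed counts, 0.11, because of Mir132, which was 1.46-fold higher in replicate 2. With TMM or DESeq2 size factors 3 genes were higher and 5 lower. Among the named genes, Mir138-1 no longer passed (adjusted p = 0.699 and 0.940 by the exact binomial test) and Mir137 passed as higher, which account for only part of the change. The activity-regulated or dendritic list behaved likewise, with 2 higher and 6 lower among 9 tested (2 and 4 with either other scaling), a median of -0.12 (percentile 21.5; -0.07 with DESeq2 size factors) and a log2 ratio of the sums of 0.28. The miR-9 family had both tested genes higher in replicate 2, at log2 ratios of 0.51 for Mir9-3 and 1.70 for Mir9-1. In the astrocyte-associated list 3 of 4 genes were higher and Mir29b-1 was lower, with Mir29c 1.82-fold higher in replicate 2 and a median of 0.17 (percentile 74.6). In the oligodendrocyte list Mir219a-2 was 1.32-fold higher in replicate 2, Mir338 was lower at a log2 ratio of -0.10, and Mir219a-1 did not pass. The list's median of 0.31 (percentile 86.7) is that of Mir219a-1 itself, with 35 and 58 counts, and was 0.15 at a minimum of 100 counts.

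The endothelial and mural list had 2 of 3 tested genes higher in replicate 2, Mir126a by 0.27 and Mir143 by 0.15 on the log2 scale, and a median of 0.15 (percentile 74.6). The choroid plexus and ependyma list had 2 of 4 higher, Mir34c 1.41-fold and Mir204 1.37-fold, and a median of 0.22 (percentile 82.5). The erythroid list had 2 of 3 higher, Mir451a 1.68-fold and Mir144 1.54-fold, and a median of 0.62 (percentile 96.2) that was 0.34 at a minimum of 100 counts. The microglia and leukocyte list had 2 of 5 higher, Mir146 1.33-fold and Mir150 1.11-fold, and its median of -0.15 (percentile 31.9) had the opposite sign to the log2 ratio of its sums, 0.23, but was -0.0025 at a minimum of 100 counts. None was lower, but Mir142 passed as lower with the deeper library thinned (adjusted p = 0.0433). The list of other organs had Mir375 higher at a log2 ratio of 0.13 (adjusted p = 0.121 with the deeper library thinned) and Mir206 2.66-fold higher in replicate 1 among 4 tested, and its median of -0.04 (percentile 50.2) turned to 0.0003 with TMM and 0.0059 with DESeq2 size factors, where Mir203 passed as higher too. The Sfmbt2 families had 3 of 8 higher and 3 lower (1 and 3 with the deeper library thinned), with a median of -0.08 (percentile 39.1) that was -0.24 at a minimum of 100 counts and -0.05 and -0.04 with TMM and DESeq2 size factors. The miR-17~92 list had 3 of 9 higher and none lower, or 2 when adjusted over the list alone, with a median of 0.03 (percentile 68.2) that was 0.07 with either other scaling. Its number of higher genes was 4 with either other scaling, where Mir93 passed, and 2 of 8 tested with the deeper library thinned, where Mir106b did not (adjusted p = 0.0857). The other lists gave the same counts adjusted over the list alone as over all genes tested. In the testis list 1 gene was tested and did not pass, and in the pluripotent list none was tested.

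Across the 420 genes the libraries had a biological coefficient of variation, the spread beyond counting error, of 0.311 as estimated by edgeR. Pearson's r across genes was 0.984 and Spearman's rho 0.979 on log2(CPM + 0.5), where genes are not independent replicates. A chi-square of 172200 on 419 degrees of freedom shows that the libraries differed far beyond sampling noise and are not 1 library deposited under 2 records. Reads on the antisense strand of a miRNA gene came to 7.14% ± 0.329 (SD, n = 2) of the sense and antisense reads together. Nearly all of them lay where another miRNA gene is annotated on the other strand, and over the 2138 genes without such a partner the share was 0.00326% ± 0.000524. At such pairs a sense read of 1 gene is also counted as antisense of its partner, so the 7.14% is mostly reads counted in both columns.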

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

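The test on low amounts of miRNA in the tissue and the restriction of the antisense reads to genes without an overlapping partner were chosen only after the results were seen. With 1 group of 2 libraries, the design allows no test for a sample far from the others or for a difference between groups. The values here therefore come from reads or columns that the comparisons do not use, each above the 3 reads that a count of 0 allows.

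Reads left out because they map to several places made up 47.1% of all reads on average, more than the reads counted on miRNA genes. The miR-124 genes had at most 13 counts in a library and the miR-9 genes at most 650, although both miRNAs are known as abundant in brain. Reads shared between gene copies are a candidate explanation: across the 18 genes of the neuron-enriched and miR-9 lists, Spearman's rho of mean CPM with the longest stretch shared with a copy was -0.713, but without the 6 miR-124 and miR-9 genes it was -0.188 over 12 genes, so the relation rests on the genes it is meant to explain. Low amounts in this tissue cannot be told apart from it, because the reads that map to several places, at least 45.9% of each library, are given as a total without gene names. The design names no group that would give a biological explanation to test.

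In replicate 2, 176083 antisense reads lay on the gene opposite Mirlet7e, the same number as the sense reads of Mirlet7e itself. These are the same reads counted in both columns, since Mirlet7e kept 0 reads in the column without regard to strand. In replicate 1 that column set aside 335206 reads as ambiguous and the antisense column held 335327, against 475885 and 476084 in replicate 2. The antisense total is therefore mostly such reads and no measure of antisense transcription. Over genes with no miRNA gene on the other strand, 0.00326% of the reads were antisense, 121 reads in replicate 1 and 200 in replicate 2. Reads given to no annotated gene made up 3.64% of all reads on average.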

How the results depend on the processing

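The antisense share without overlapping genes and the counts of 2-fold genes after GC correction and without gene copies were chosen after the data were seen, the other alternatives before. Among the genes picked by the naming rule, Mir138-1 and Mir221 lost their calls under TMM and DESeq2 size factors. Mir375 and Mir106b lost theirs on thinning. Mir93 and Mir137 gained one under both scalings, Mir203 under DESeq2 size factors and Mir142 on thinning. Other genes outside the naming rule also lost their calls under each of these settings and are not listed. A minimum of 100 counts left 270 genes detected instead of 420. A 2-fold minimum left 41 of 239 differing genes, by its construction, while TMM, DESeq2 size factors and no filter gave 236 to 249 and thinning stayed within 1.5 times. Mir221 went from -0.03 to 0.003 (TMM) and 0.0086 (DESeq2), no longer different from 0, and Mir137 from -0.0008 to 0.0367 and 0.0423 with a call, both within the shift of 0.0372 or 0.0428 in the median of all tested genes; list medians moved by about this shift too, and that of other organs changed sign. Mir449a, without a call, turned from -0.01 to 0.0272 and 0.0328, and Mir137 to 0.0076 without regard to strand. Among the 239 genes only Mir221 had a value of the other sign under TMM or DESeq2 size factors. At a minimum of 100 counts the list medians became 0.1532 (oligodendrocyte), 0.3385 (erythroid), -0.0025 (microglia) and -0.2359 (Sfmbt2), by the loss of tested members. Without regard to strand, where reads on overlapping genes are dropped, the top 10 share was 59.564% and list shares were neuron-enriched 5.5614%, astrocyte 1.8388%, oligodendrocyte 0.0%, endothelial 0.9032%, erythroid 0.002085%, other organs 0.048035%, Sfmbt2 0.16054%, miR-17~92 0.33417% and testis 0.001189%. Without Mirlet7g in the denominator, which raises other shares by construction, they were neuron-enriched 5.9917%, activity-regulated 3.5857%, astrocyte 1.9384%, oligodendrocyte 0.77187%, microglia 0.2187%, endothelial 2.373%, other organs 0.050615%, let-7 28.744%, Dlk1-Dio3 11.644%, Sfmbt2 0.16917%, miR-17~92 0.35221% and testis 0.001253%. The antisense share was 8.0745% without the most abundant gene and 0.003263% without overlapping genes. Leaving out a replicate gives the share of the other library, which with 2 libraries says nothing about stability; the list of regions outside hippocampus went from 0.0448% to 0.0227% without replicate 1 and 0.0668% without replicate 2. It gave no value for differences, spread, correlation or list ratios. The coefficient of variation ranged from 0.311 to 0.330. Depth limits calls of small differences: 54.2% of simulated 1.2-fold changes were called. No paired analysis was possible because there is 1 group.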

Other observations

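The miRNA families described next, the test of neighbouring genes in both its forms, the test for tissue from outside the hippocampus, the correction for GC content and the restriction to genes without copies were chosen after the data were seen.

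Beyond the fixed lists, several families held large shares of the counts. The miR-99, miR-100 and miR-125 genes, partners of let-7 genes in shared clusters, held 5.51% ± 0.0852 (SD, n = 2) of the counts, of which Mir99a and Mir125a made up 2.66% and 1.83%. The miR-23, miR-27 and miR-24 clusters held 3.40% ± 0.430, with Mir23b at 22717 CPM and Mir27b at 2624 CPM. The miR-221 and miR-222 genes held 1.39% ± 0.243 and the miR-30 family 1.34% ± 0.226. The miR-26 family held 0.847% ± 0.138, nearly all from Mir26b at 8163 CPM. The miR-181 family held 0.536% ± 0.0105, led by Mir181c at 1979 CPM, and the genes of miR-15, miR-16, miR-195 and miR-497 held 0.513% ± 0.0544. These shares and ranks hold among reads that map to 1 place. The miR-23, miR-27, miR-24, miR-125b, miR-30c, miR-26a, miR-181a, miR-181b and miR-16 genes share 20 to 30 bases with a copy, so they and the shares of their families are uncertain. By position, the miRNA genes of chromosome 9 held 15.0% ± 0.957 of the counts, those of chromosome 15 12.1% ± 0.620 and those of chromosome 12 10.5% ± 1.01.

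Many closely spaced genes on 1 strand had log2 ratios of opposite sign between the replicates, and 2 pairs are given as examples. Mir195a had a log2 ratio of 1.13 in replicate 2 over replicate 1, while Mir497, which lies 241 bases away on chromosome 11, had -0.72. Mir298 had 1.48 and Mir296, 378 bases away on chromosome 2, had -0.39.

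The 41 genes that differed 2-fold or more between the libraries were weighed against 3 explanations. A lowess correction on hairpin GC content left 42 genes, 102.4% of the number, with 38 shared. Corrections on shuffled GC content left 39 to 44. This argues against hairpin GC content as the main source. A weak trend was present, with Spearman's rho of -0.152 between log2 ratio and GC content over the tested genes. The GC content of the sequenced arm was not examined. Of the 41, 82.9% (95% Wilson interval 68.7 to 91.5) share fewer than 20 bases with a copy. That share alone decides little, because most tested genes share as few. Differences of 2-fold or more were found in 10.1% of tested genes below 20 shared bases and in 8.54% of those with 20 or more. They were thus no more common among genes with copies, which argues against copies as the main source. A difference in whole primary transcripts may contribute, though this was tested over 150 clustered genes at any fold and not over the 41 as a set. The log2 ratios of 107 neighbouring pairs within 10000 bases differed by 0.596 on average, against a shuffle median of 0.708. Of 10000 shuffles, 0.2% gave a value as small (0.05% without the Dlk1-Dio3 pairs). A product of the neighbours' deviations, tried after that result because noise levels may cluster too, was as high in 3.06% of shuffles, with Pearson's r of 0.199 across pairs (0.74% and 0.338 without the Dlk1-Dio3 pairs). Opposed signs were not limited to the 2 pairs above and occurred in many of the 107 pairs. Mir99b and Mirlet7e, 94 bases apart, had log2 ratios of -0.88 and 0.13, whereas Mir182 and Mir183 agreed in sign. The opposed pairs go against whole transcripts as the only source, and whether the tissues came from different animals stays open.

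The 10 tested genes of the list of regions outside hippocampus were 10 of 10 lower in replicate 2, Mir10a within counting error. Most of them are close neighbours, so they are not 10 independent results. RNA from intestinal epithelium in replicate 1 would bring miR-192, miR-194 and miR-215, but the median log2 ratio of the 2 tested genes of that list of 4, Mir194-2 at 35.1 CPM and Mir192 at 14.5 CPM, was 0.25. Mir194-2 shares 22 bases with a copy and is uncertain, while Mir192 shares 13 and had a log2 ratio of 0.20 (95% interval -0.28 to 0.69). These 2 genes lie 115 bases apart, so they are 1 cluster at low levels and argue only weakly against intestinal RNA. After GC correction the median of the pattern stayed at -1.35, which argues against hairpin GC content. Tissue from outside the hippocampus taken along in replicate 1 may account for the pattern. It cannot be told apart from a difference between the hippocampi, because no independent marker list for such tissue was written. Among markers of other tissues, Mir34c, Mir204 and Mir451a were 1.41-fold, 1.37-fold and 1.68-fold higher in replicate 2, and Mir126a was higher by a log2 ratio of 0.27. In the same lists, Mir34b (-0.37), Mir449a (-0.01), Mir486 (-0.07) and Mir145a (-0.08) had negative log2 ratios and did not pass the threshold. In the list of other organs, Mir206 was 2.66-fold higher in replicate 1, while Mir375 was higher in replicate 2 by a log2 ratio of 0.13. Mir203 (0.17) and Mir122 (-0.20) did not pass the threshold at total counts. The design names no group that would give a biological explanation to test.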
